A study of Mus musculus with 12 samples.

How the data were processed

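Gene expression was measured with Affymetrix Gene ST arrays in inflammatory monocytes of the mouse spleen, 3 mice in each of 4 groups. Per the labels' protocols, spleens of female mice that carry a CCR2 reporter were dissociated at 37 °C with collagenase and DNase, CD11b-positive cells were enriched with magnetic beads, and reporter-positive cells negative for NK, neutrophil, B cell and T cell surface markers were sorted. Isolation took place on several days, and the labels do not tie a mouse to a day.

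The authors deposited 1 table of log2 expression values for 28944 probe sets and 12 arrays. Per the submitters' processing notes the values were made by RMA, which corrects for background, normalizes between arrays and summarises probes into probe sets, with the oligo package, and were tested with limma. Versions of these tools and the genome build behind the array are not given in the sources used here. The deposited log2 values were used as they stand, with no rescaling. Their median was 4.08.

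Probe sets were joined to genes by the table of probe sets supplied with the reference. Of the 28944 probe sets, 21789 carried 1 gene symbol, 1621 carried several and 5534 carried none, and 21698 took a current symbol through their gene identifier from a RefSeq table of the assembly GRCm38.p6. No coordinates were used. For the 999 genes with more than 1 probe set, the probe set with the highest mean was kept, which left 19938 genes. The other 9006 probe sets were tested only in a fit of all probe sets together. Arrays give no count or depth, and the number of arrays limits the precision of every value; the median standard error of a difference was 0.21 on the log2 scale.

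Groups were compared with limma 3.58.1 in R 4.3.3, with a linear model of 4 group means (8 residual degrees of freedom, to which the moderation of variances added 4.82), 6 contrasts and an F test of any difference. Values of p were adjusted by the Benjamini-Hochberg method over the genes of each contrast, and a gene is said to have risen or fallen when its adjusted p was under 0.05. All p-values are two-sided. Each group enters 3 of the 6 comparisons, so that the comparisons share arrays. Shared genes and correlations between comparisons are given with the mean of 100 simulations without any effect, in which the same numbers of genes were taken by rank of the moderated t. For shared genes the number expected of independent comparisons is given as well.

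The 32 gene lists cover the interferon gamma response, type I interferon, MHC class I, MHC class II with co-stimulation, inflammatory cytokines, chemokine ligands, NF-kB targets, IL-15 with TNF superfamily ligands, pattern recognition, antimicrobial effectors, scavenger receptors, monocyte identity, nonclassical monocytes, alternative activation, glycolysis, oxidative phosphorylation, cholesterol synthesis, cell cycle, apoptosis, the unfolded protein response, ribosomal proteins, migration receptors, dissociation stress and markers of 9 other cell types. Of the 599 genes listed, 525 were measured. The lists were tested against all other genes with camera at its preset correlation of 0.01 between genes, and again with an estimated correlation, which gives larger p-values. A list is called when camera's adjusted p at the preset correlation was under 0.05, and the p with an estimated correlation is given beside it. The fry test, which asks whether the genes of a list move one way on balance without setting them against other genes, was a further alternative. Mean list values per array were compared by exact two-sided permutation tests, whose smallest possible p for 3 arrays against 3 is 0.1.

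The groups, comparisons, lists, alternatives and rule for naming genes were fixed before the data were examined. The rule names, for each comparison, the 8 genes with the largest positive and the 6 with the most negative difference among those past the threshold whose 3 arrays of one group all lie above the 3 of the other, leaving out predicted genes and small RNAs. It also names up to 4 called members of each list described, and a fixed set of 14 genes, of which 13 were measured. A gene outside the rule is said to have been chosen after its values were seen.

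The alternatives were a replicate block, a filter on dim genes (11794 genes kept), all probe sets tested together, the mean of a gene's probe sets, median centring, quantile normalization, a variance trend with robust moderation, array weights, a test against a minimum fold of 1.5, each comparison fitted on its 2 groups alone, and each array left out in turn. The covariate for the spread of an array's values, the fit without the 4 arrays numbered 2 and the fit of 11 arrays without primary array 2 were added after the data were seen. The procedure was tested on simulated data with the same number of arrays and genes. Of genes given a difference of 1, 2, 3 or 4 on the log2 scale between secondary and primary infection, 54.0%, 92.2%, 97.2% and 99.4% were called, and 5.91% of the calls were false. With no simulated difference, limma called 0 genes between primary infection and the uninfected state. A shifted list was called in 10 of 10 runs. The simulated noise was independent between genes, whereas genes of the real arrays vary together with the spread of an array's values. Each run also changed 50 genes of each size, whereas the adjusted threshold is stricter where fewer genes differ. These rates therefore need not hold for the real comparisons. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.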

Results

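Expression was measured in Ly6C-positive inflammatory monocytes, blood-derived phagocytes that need the chemokine receptor CCR2 to leave the bone marrow, sorted from the spleens of uninfected mice and of mice infected with Listeria monocytogenes, a bacterium that lives inside host cells. The 12 arrays came from 3 uninfected mice, 3 mice taken 8 h after a primary infection (labelled dose 10e6), 3 mice taken 8 h after the same dose given 5 weeks after a smaller infection (labelled dose 10e4), and 3 mice treated like the last group but depleted of T cells 1 day before the challenge. These groups are called uninfected, primary, secondary and T cell-depleted secondary. Values are log2 expression, and a difference of 1 is a doubling. The median value of an array lay between 3.96 and 4.20. Across the 4 groups, 84 of 19938 genes differed by the F test, the smallest adjusted p being 3.87e-05.

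The comparison of primary infection with the uninfected state asks what 8 h of a single infection does to these monocytes. The neutrophil-attracting alarmin gene S100a8 rose by 4.34 (SE 0.51, adjusted p = 0.0235), from 5.63 ± 1.38 to 9.97 ± 0.16 (SD, n = 3 per group). Cxcl10, which encodes a chemokine for activated T cells, rose by 2.77 (SE 0.35, adjusted p = 0.0310), from 5.97 ± 0.56 to 8.74 ± 0.48. Jun, an immediate early transcription factor gene, rose by 2.44 (SE 0.33, adjusted p = 0.0348). These were the only genes that limma called, 3 higher and 0 lower, whereas 629 had an unadjusted p under 0.05. Groups did not overlap for 6.40% of genes, where chance gives 10%. Differences that did not pass were 2.55 for Cxcl9 (adjusted p = 0.129) and 2.42 for Il1b (adjusted p = 0.0744). The other fixed genes had an adjusted p of 0.999, with differences of 1.25 for Irf1, 1.12 for Il6 (uninfected arrays at 2.97, below the median of all values of 4.08), 0.73 for Tnf, 0.42 for Ifit1, 0.41 for Ccr2, 0.21 for Ciita, -0.11 for Il15, -0.18 for Ifng, -0.19 for Nos2 and -0.22 for Il12b. Ifng and Il12b lay below that median in all 4 groups and Nos2 in all but secondary infection, so that their differences, here and in the other comparisons, are those of values near background. Limma called 0 genes without uninfected array 1 (378 at unadjusted p under 0.05), uninfected array 2 (399) or primary array 3 (420), 1 without primary array 1 and 13 without primary array 2. With median centring limma called 0 genes (703 at unadjusted p under 0.05) and with quantile normalization 5. With array weights 2887 genes were higher and 5211 lower. With the 2 groups alone 1 gene was called, none of these 3, and with the 8 arrays without number 2 it was 4, with Jun but without S100a8 and Cxcl10.

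By list, 13 of 32 were called higher in primary infection and 0 lower. Of the calls, 2 held with an estimated correlation, and fry called 0 lists for a shift one way and 5 for change in either direction. The chemokine list rose by a mean of 0.72 (camera adjusted p = 6.21e-08, adjusted p = 0.0451 with an estimated correlation), with 1 of 18 genes higher over all genes and 3 higher adjusted over the list alone. The dissociation stress list, immediate early genes that enzymatic tissue digestion also induces, rose by 0.87 (adjusted p = 9.47e-16, and 0.0451 with an estimated correlation). Of its 17 genes, 1 was higher over all genes and 6 adjusted over the list alone. Among these were Fosb (2.55, from 3.89, below the median of all values), Fos (2.37), Atf3 (2.02) and Jun. The remaining calls were lost with an estimated correlation. Inflammatory cytokines rose by 0.49 (adjusted p = 0.0556 with an estimated correlation), with 0 of 20 genes called over all genes and 4 higher adjusted over the list alone: Il1b, Ptgs2 (2.20), Osm (1.68) and Il1rn (0.94). The interferon gamma list rose by 0.59 (adjusted p = 0.178 with an estimated correlation; 1 of 21 genes over all genes and 5 adjusted over the list alone). Antimicrobial effectors rose by 0.60 (adjusted p = 0.178 with an estimated correlation; 1 of 21 genes and 3 adjusted over the list alone). NF-kB targets rose by 0.52 (adjusted p = 0.219 with an estimated correlation) and type I interferon genes by 0.30 (adjusted p = 0.467 with an estimated correlation). Further rises were those of pattern recognition (0.34, adjusted p = 0.262 with an estimated correlation), neutrophil markers (0.25, adjusted p = 0.178 with an estimated correlation) and the unfolded protein response (0.24, adjusted p = 0.188 with an estimated correlation). The smallest were those of oxidative phosphorylation (0.21, adjusted p = 0.468 with an estimated correlation), cell cycle (0.21, adjusted p = 0.178 with an estimated correlation) and cholesterol synthesis (0.16, adjusted p = 0.262 with an estimated correlation).

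The comparison of secondary infection with the uninfected state gives the change after an earlier infection and a challenge together. No group had the earlier infection without the challenge. A lasting effect of the earlier infection therefore cannot be told apart from the response to the challenge. Cxcl10 rose by 5.56 (SE 0.35, adjusted p = 8.12e-06), from 5.97 ± 0.56 to 11.53 ± 0.43 (SD, n = 3 per group). Iigp1, an interferon gamma-induced GTPase gene that acts on vacuoles holding pathogens, rose by 5.08 (SE 0.33, adjusted p = 8.12e-06), from 4.38 ± 0.38 to 9.46 ± 0.33. The guanylate-binding protein genes Gbp4 and Gbp5 rose by 5.19 and 4.30, the prostaglandin synthase gene Ptgs2 by 5.12, the itaconate-producing enzyme gene Acod1 by 4.91, Cxcl9 by 4.66 and S100a8 by 4.47. Serpinb10 fell by 3.83 (SE 0.69, adjusted p = 0.0211) to 3.79 ± 0.90, below the median of all values (4.08), so that the size of the fall rests on a value near background. The prostaglandin-degrading enzyme gene Hpgd fell by 3.06 (SE 0.33, adjusted p = 4.19e-04) and Cx3cr1, the fractalkine receptor gene that marks nonclassical monocytes, also fell by 3.06 (SE 0.35, adjusted p = 6.96e-04). Falls were also called for Glipr1 (-2.93), St8sia4 (-2.53) and Ace (-2.47). In all, 153 genes changed, 121 higher and 32 lower, and 118 and 31 of them by at least 2-fold. Groups did not overlap for 11.4% of genes, where chance gives 10%. With median centring 61 genes were higher and 13 lower, with quantile normalization 160 and 84, and with array spread as a covariate, chosen after the data were seen, 295 and 273. With array weights 639 were higher and 531 lower. The count was 68 without uninfected array 1, 99 without uninfected array 2, 93 without secondary array 1, 96 without secondary array 3 and 131 without secondary array 2.

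Of the fixed genes, Il1b (3.19, adjusted p = 7.61e-04), Irf1 (3.15, adjusted p = 0.0361) and Tnf (2.57, adjusted p = 0.00862) also rose in secondary infection relative to the uninfected state. Il6 (3.19, adjusted p = 0.0811; uninfected arrays at 2.97, near background) and Ifit1 (2.05, adjusted p = 0.0754) did not pass. Nor did Nos2 (0.53), Ciita (0.25), Ifng (0.19), Il12b (0.12), Il15 (-0.60) and Ccr2 (-0.69).

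The lists called higher in secondary infection relative to the uninfected state numbered 16, and 1 was lower. Of these calls 7 held with an estimated correlation, and fry called 11 lists for a shift one way and 20 for change in either direction. The interferon gamma list rose by a mean of 2.60 (camera adjusted p = 1.83e-45, and 0.00218 with an estimated correlation), with 13 of 21 genes higher over all genes and 17 adjusted over the list alone. Chemokines rose by 1.53 (adjusted p = 0.00218 with an estimated correlation), with Cxcl10, Cxcl9, Cxcl2 (3.84) and Cxcl11 (2.84) among them. Cxcl2 was at 4.11 ± 0.46 in uninfected arrays, near the median of all values (4.08), so that the size of its rise is uncertain. Of the 18 chemokine genes, 5 were higher over all genes. Adjusted over the list alone 11 were higher and Ccl9 (-1.21) was lower. NF-kB targets rose by 1.20 (adjusted p = 0.0408 with an estimated correlation; 5 of 18 genes over all genes and 12 adjusted over the list alone). The feedback genes Tnfaip3 (3.22), Dusp1 (2.86) and Nfkbia (2.19) were among them. Inflammatory cytokines rose by 1.16 (adjusted p = 0.00218 with an estimated correlation; 5 of 20 genes and 7 adjusted over the list alone). Il1b and the antagonist gene Il1rn (2.61) were among these. Antimicrobial effectors rose by 1.04 (adjusted p = 0.0335 with an estimated correlation; 3 of 21 genes and 8 adjusted over the list alone). MHC class I genes rose by 0.76 (adjusted p = 0.0430 with an estimated correlation). Of 16 genes 0 were called over all genes and 4 adjusted over the list alone, the antigen-processing genes Tap1 (1.87), Tap2 (1.15), Tapbpl (0.91) and Psme1 (0.90). The unfolded protein response rose by 0.55 (adjusted p = 0.0335 with an estimated correlation; 0 of 16 genes and 6 adjusted over the list alone).

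Other list calls of that comparison were lost with an estimated correlation. Type I interferon genes rose by 1.00 (adjusted p = 0.0756 with an estimated correlation). All 25 of 25 were positive, with Ifit2 (3.35) called over all genes and 8 adjusted over the list alone. The dissociation stress list rose by 0.69 (adjusted p = 0.0864 with an estimated correlation), including Jun (2.16), Fos (1.91) and Egr1 (1.13). MHC class II with co-stimulation rose by 0.45 (adjusted p = 0.269 with an estimated correlation), with 10 of 13 genes positive and Cd86 (2.23) and Cd40 (1.58) called over all genes. Glycolysis rose by 0.48 (adjusted p = 0.115 with an estimated correlation) with Hif1a (2.35) and Pfkp (2.27). Pattern recognition rose by 0.39 (adjusted p = 0.238 with an estimated correlation) with Clec4e (2.82) and Nlrc4 (0.98, from 3.96, below the median of all values). Alternative activation rose by 0.42 (adjusted p = 0.0649 with an estimated correlation) and apoptosis by 0.30 (adjusted p = 0.188 with an estimated correlation). The list of IL-15 and TNF superfamily ligands rose by 0.27 (adjusted p = 0.0595 with an estimated correlation) and oxidative phosphorylation by 0.20 (adjusted p = 0.629 with an estimated correlation). The nonclassical monocyte list was lower, with a mean of -0.67 (adjusted p = 0.115 with an estimated correlation). Cx3cr1 and Ace were called among its 13 genes, and 5 genes adjusted over the list alone.

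The comparison of secondary with primary infection asks how monocytes differ after challenge when the mouse has met the bacterium before. Without a group that had the earlier infection alone, a different response cannot be told apart from differences present before the challenge. Of the 52 higher genes, 8 belonged to the interferon gamma list. Iigp1 was at 9.46 ± 0.33 in secondary and 4.73 ± 0.44 in primary infection (SD, n = 3 per group), a rise of 4.72 (SE 0.33, adjusted p = 4.87e-05). Gbp4 rose by 4.55 (SE 0.51, adjusted p = 0.00193), from 5.40 ± 0.83 to 9.95 ± 0.66. The complement factor gene Cfb rose by 3.93 (SE 0.59, adjusted p = 0.0122) and Acod1 by 3.61 (SE 0.45, adjusted p = 0.00379). Cd274, which encodes the inhibitory ligand PD-L1, rose by 3.08, Gbp5 by 3.03, Ptgs2 by 2.92, the actin-binding calponin gene Cnn3 by 2.88 and Cxcl10 by 2.79. Cx3cr1 fell by 2.75 (SE 0.35, adjusted p = 0.00379), from 8.52 ± 0.62 to 5.77 ± 0.63. The translation inhibitor gene Pdcd4 (-2.02, to 4.14, near the median of all values), the lectin gene Clec4a3 (-1.78), Hpgd (-1.72), the adhesion receptor gene Ceacam1 (-1.67) and the linker histone gene H1f2 (-1.40) also fell. Of 63 genes past the threshold 52 were higher and 11 lower, all by at least 2-fold. Groups did not overlap for 13.1% of genes, where chance gives 10%. Of the fixed genes only Cxcl10 passed. The values were 2.12 for Cxcl9 (adjusted p = 0.0718), 2.07 for Il6, 1.90 for Irf1, and 1.84 for Tnf (adjusted p = 0.0969). Further values were 1.64 for Ifit1, 0.77 for Il1b, 0.72 for Nos2, 0.37 for Ifng, 0.34 for Il12b, 0.04 for Ciita, -0.49 for Il15 and -1.10 for Ccr2. With median centring 23 genes were higher and 5 lower, with quantile normalization 99 and 41, and with array spread as a covariate, chosen after the data were seen, 205 and 143. With array weights 999 were higher and 1272 lower. The count was 29 without primary array 3, 37 without primary array 1, 40 without secondary array 1, and 39 without secondary array 3. It was 91 without primary array 2, of which 39 were higher and 52 lower.

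**Figure D1:**
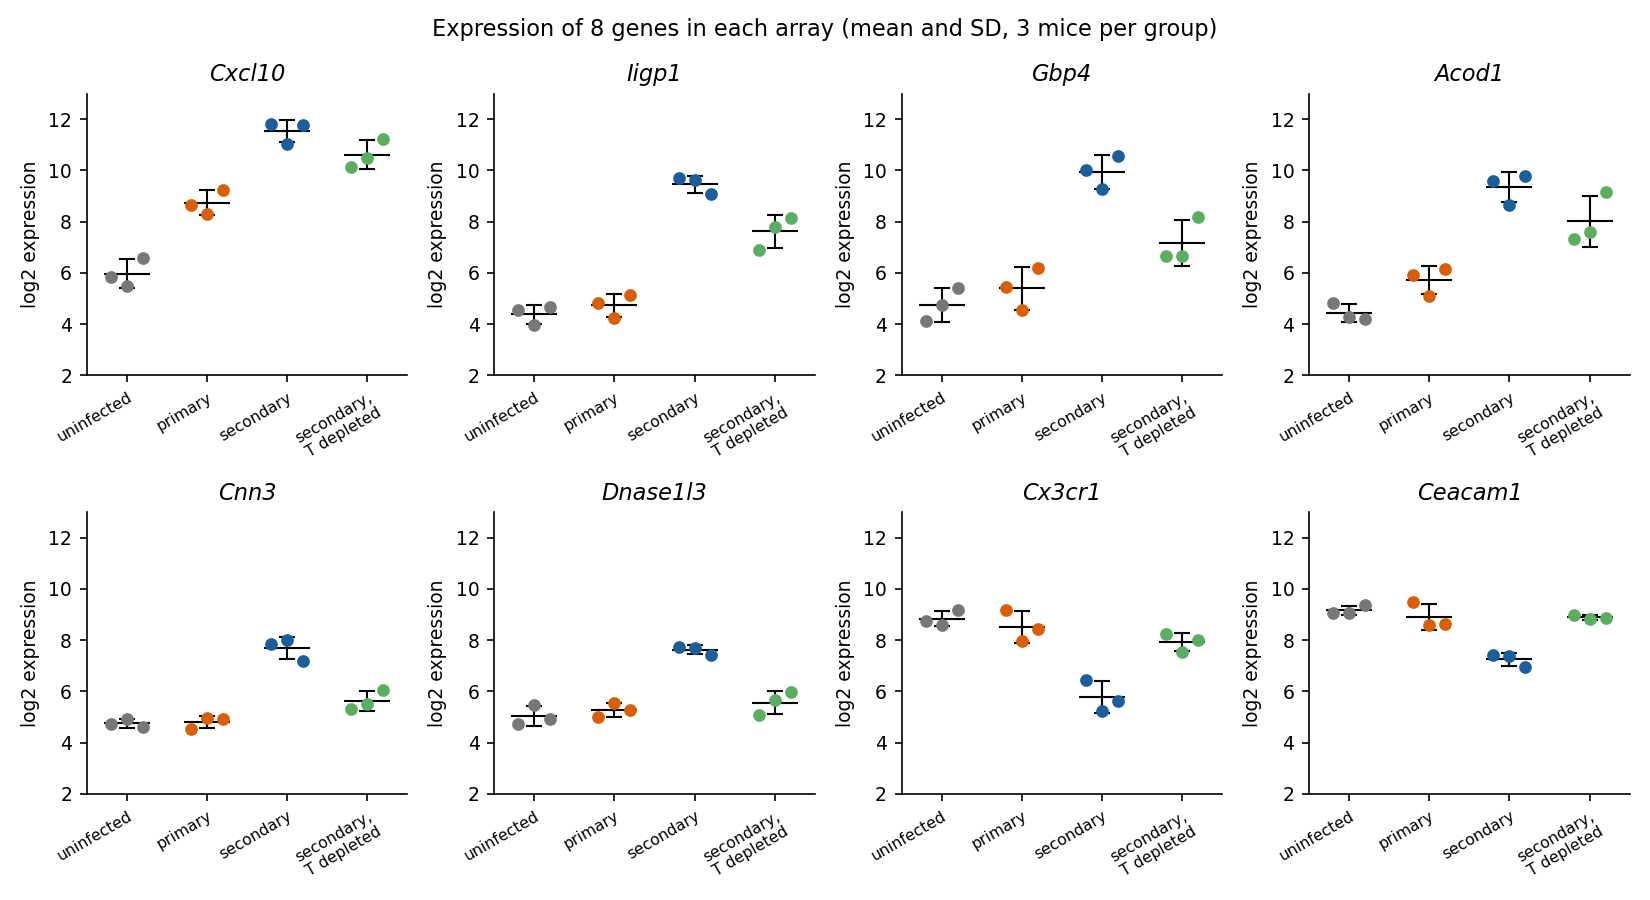
Each panel shows log2 expression of 1 gene in the 12 arrays, grouped as uninfected, primary, secondary and T cell-depleted secondary (points are mice, bars are the mean and SD, n = 3 per group). Iigp1 has means of 4.38, 4.73, 9.46 and 7.62 in that order, and Cx3cr1 is lowest in the secondary group at 5.77.

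Between secondary and primary infection, 10 lists were called higher and 3 lower. With an estimated correlation 3 of these calls held, and fry called 3 lists for a shift one way and 13 for change in either direction. Interferon gamma response genes were higher by a mean of 2.01 (camera adjusted p = 2.23e-30, and 0.0251 with an estimated correlation), with 8 of 21 genes higher over all genes and 17 adjusted over the list alone. Chemokines rose by 0.81 (adjusted p = 0.0267 with an estimated correlation), with Cxcl10 and Cxcl11 (2.22) called over all genes. Of 18 genes adjusted over the list alone, 8 rose and Ccl9 (-1.35) fell. Inflammatory cytokines rose by 0.67 (adjusted p = 0.0267 with an estimated correlation), with 15 of 20 genes positive and Ptgs2 and Il1rn (1.67) called over all genes. Calls lost with an estimated correlation were those of type I interferon genes (0.70, adjusted p = 0.377 with an estimated correlation; Ifit2, 2.18), MHC class I (0.70, adjusted p = 0.180 with an estimated correlation) and NF-kB targets (0.68, adjusted p = 0.376 with an estimated correlation; Tnfaip3, 2.74). So were those of antimicrobial effectors (0.44, adjusted p = 0.376 with an estimated correlation) and glycolysis (0.37, adjusted p = 0.410 with an estimated correlation; Pfkp, 1.83, and Hif1a, 1.75). The same held for the unfolded protein response (0.31, adjusted p = 0.376 with an estimated correlation) and alternative activation (0.28, adjusted p = 0.394 with an estimated correlation). Lower lists were nonclassical monocyte (-0.50, adjusted p = 0.376 with an estimated correlation), ribosomal proteins (-0.21, adjusted p = 0.532 with an estimated correlation) and cell cycle (-0.17, adjusted p = 0.394 with an estimated correlation).

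The comparison of secondary infection with and without T cells asks which part of the monocyte response needs T cells at the time of challenge. Dnase1l3, a secreted DNase gene, was higher with T cells by 2.07 (SE 0.25, adjusted p = 0.0193), at 7.63 ± 0.17 against 5.57 ± 0.45 (SD, n = 3 per group). Cnn3 was higher by 2.06 (SE 0.25, adjusted p = 0.0193), at 7.69 ± 0.44 against 5.63 ± 0.39, and the uridine phosphorylase gene Upp1 by 1.90 (SE 0.27, adjusted p = 0.0449), at 6.01 ± 0.08 against 4.11 ± 0.60, the latter near the median of all values (4.08). Ceacam1 was lower with T cells by -1.64 (SE 0.23, adjusted p = 0.0449), at 7.25 ± 0.25 against 8.89 ± 0.09. No other gene passed, while 728 had an unadjusted p under 0.05 and groups did not overlap for 8.21% of genes, where chance gives 10%. None of the 13 fixed genes was called, each with an adjusted p of 1.00. Their differences were 1.12 for Irf1, 0.91 for Cxcl10, 0.76 for Tnf, 0.68 for Cxcl9, 0.60 for Il6 and 0.52 for Il1b. They were 0.49 for Ifit1, 0.48 for Nos2, 0.41 for Ciita, 0.26 for Ifng, -0.08 for Il12b, -0.74 for Ccr2 and -0.95 for Il15. Quantile normalization gave 4 higher and 6 lower genes, median centring 2 and 0, and array spread as a covariate, chosen after the data were seen, 39 and 22. Array weights gave 90 and 42, and the 2 groups alone, the minimum fold and the 8 arrays without number 2 gave 0. Limma called 0 genes without secondary array 1 (795 at unadjusted p under 0.05), depleted array 1 (520) or depleted array 2 (721), 1 without secondary array 2 or secondary array 3, and 12 without depleted array 3.

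The interferon gamma list was higher with T cells by a mean of 1.12, positive in 21 of 21 genes (camera adjusted p = 1.46e-25, and 0.0433 with an estimated correlation; fry adjusted p = 0.0706). Over all genes 0 of its members passed, and 12 were higher adjusted over the list alone. These were Gbp4 (2.78), Gm4951 (2.33), Gbp8 (1.90), Iigp1 (1.84), Cd274 (1.69), Gbp5, Gbp7 (1.48), Icam1 (1.32), Jak2 (1.03), Gbp9 (0.96), Cxcl10 (0.91) and Irf8 (0.85). The mean value of the list was 5.29 ± 0.29 in uninfected, 5.88 ± 0.31 in primary, 7.89 ± 0.36 in secondary and 6.77 ± 0.47 in T cell-depleted secondary arrays. The last 2 groups did not overlap (exact permutation p = 0.1, the smallest possible). Type I interferon genes differed by 0.03 with and without T cells (camera adjusted p = 0.966), at 7.60 ± 0.25 and 7.56 ± 0.45, with 13 of 25 genes positive (exact permutation p = 1). The mean of the interferon gamma list minus that of the type I list was higher with T cells by 1.09 (exact permutation p = 0.1, the smallest possible), a difference of the lists chosen after their values were seen. The nonclassical monocyte list was lower with T cells, by -0.76 (adjusted p = 5.63e-13, and adjusted p = 0.125 with an estimated correlation), at 5.89 ± 0.16 against 6.64 ± 0.24. Over all genes 0 of its 13 members passed, and 7 were lower adjusted over the list alone, among them Ace (-2.16), Cx3cr1 (-2.15), Pou2f2 (-1.03) and Spn (-1.00).

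**Figure D2:**
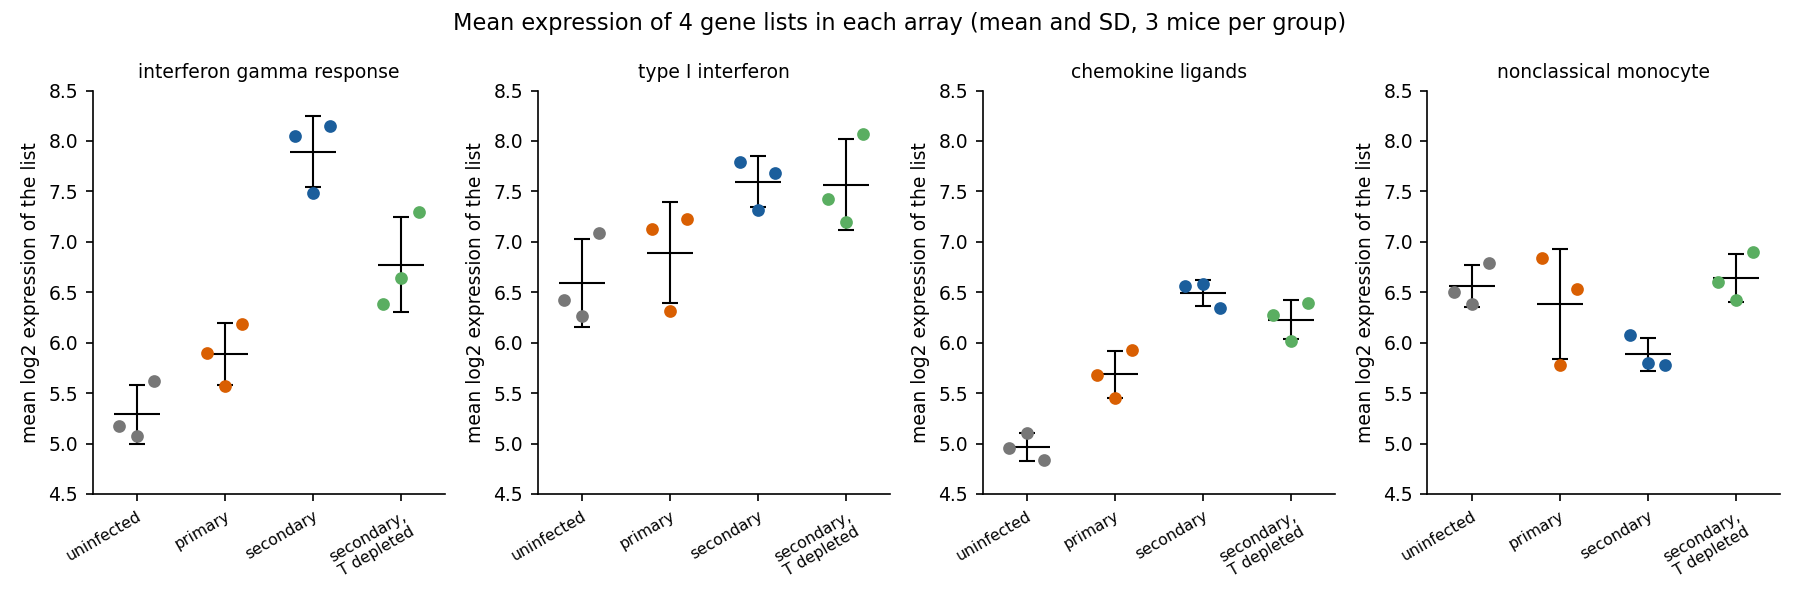
Each panel shows the mean log2 expression of the measured genes of 1 list in the 12 arrays, by group (points are mice, bars are the mean and SD, n = 3 per group). The interferon gamma list falls from 7.89 in secondary to 6.77 in T cell-depleted secondary arrays, while the type I interferon list has means of 7.60 and 7.56.

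In that comparison 10 lists were called higher with T cells and 1 lower. Only the interferon gamma list held with an estimated correlation, while fry called 0 lists for a shift one way and 5 for change in either direction. The other higher lists were MHC class I (0.51, adjusted p = 0.169 with an estimated correlation), antimicrobial effectors (0.40, adjusted p = 0.169 with an estimated correlation), and MHC class II with co-stimulation (0.36, adjusted p = 0.418 with an estimated correlation). Further calls were those of inflammatory cytokines (0.33, adjusted p = 0.169 with an estimated correlation), NF-kB targets (0.33, adjusted p = 0.734 with an estimated correlation) and glycolysis (0.32, adjusted p = 0.303 with an estimated correlation). The remaining ones were chemokines (0.27, adjusted p = 0.169 with an estimated correlation), the unfolded protein response (0.27, adjusted p = 0.169 with an estimated correlation) and alternative activation (0.25, adjusted p = 0.169 with an estimated correlation). Adjusted over the list alone, Pfkp (1.63) and Hif1a (1.49) of the glycolysis list and Cxcl11 (1.41) of the chemokine list were higher.

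The comparison of T cell-depleted secondary infection with the uninfected state gives the change seen without T cells. The labels give the uninfected mice no earlier infection and no depletion. Challenge, earlier infection and depletion therefore differ together here, and their effects cannot be told apart. Cxcl10 rose by 4.65 (SE 0.35, adjusted p = 1.64e-04), from 5.97 ± 0.56 to 10.62 ± 0.57 (SD, n = 3 per group). Cxcl9 rose by 3.98, Acod1 by 3.58, Ptgs2 by 3.42, Cxcl2 by 3.37, S100a8 by 3.35, Iigp1 by 3.23 and Ifit2 by 2.93. Cxcl2 started at 4.11 ± 0.46, near the median of all values (4.08), so that the size of its rise is uncertain. Hpgd was the only gene that fell, by -2.72 (SE 0.33, adjusted p = 0.00318). Of 20 genes called, 19 were higher and 1 lower. Of all genes, 647 had an unadjusted p under 0.05, and groups did not overlap for 6.75% of genes, where chance gives 10%. Of the other fixed genes Il1b rose by 2.68 (adjusted p = 0.0115). Values that did not pass were 2.58 for Il6 (adjusted p = 0.691, from 2.97, near background), 2.04 for Irf1, 1.81 for Tnf (adjusted p = 0.285), 1.56 for Ifit1, 0.35 for Il15, 0.19 for Il12b, 0.06 for Nos2, 0.05 for Ccr2, -0.07 for Ifng and -0.17 for Ciita. With median centring 10 genes were higher and 1 lower, with quantile normalization 20 and 3, and with array spread as a covariate, chosen after the data were seen, 40 and 10. With array weights 414 were higher and 340 lower. The count was 13 without uninfected array 1, depleted array 1 or depleted array 3.

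Of the lists, 15 were called higher in T cell-depleted secondary infection than in the uninfected state and 1 lower. The calls held for 7 of them also with an estimated correlation, and fry called 3 for a shift one way and 8 for change in either direction. Interferon gamma response genes rose by 1.48 (adjusted p = 0.0126 with an estimated correlation; 5 of 21 genes over all genes and 12 adjusted over the list alone). Chemokines rose by 1.26 (adjusted p = 0.00213 with an estimated correlation; 3 of 18 and 8 adjusted over the list alone). Type I interferon genes rose by 0.97 (adjusted p = 0.0422 with an estimated correlation; 1 of 25 and 9 adjusted over the list alone), and NF-kB targets by 0.87 (adjusted p = 0.0422 with an estimated correlation; 0 of 18 and 6 adjusted over the list alone). Dissociation stress genes rose by 0.85 (adjusted p = 0.0422 with an estimated correlation; 0 of 17 and 6 adjusted over the list alone). Inflammatory cytokines rose by 0.84 (adjusted p = 0.00213 with an estimated correlation; Il1b, Ptgs2 and Il1rn, 1.65) and IL-15 and TNF superfamily ligands by 0.22 (adjusted p = 0.0422 with an estimated correlation). Calls lost were those of antimicrobial effectors (0.64, adjusted p = 0.0977 with an estimated correlation), pattern recognition (0.33, adjusted p = 0.265 with an estimated correlation; Clec4e, 2.29) and the unfolded protein response (0.27, adjusted p = 0.207 with an estimated correlation). So were those of MHC class I (0.25, adjusted p = 0.302 with an estimated correlation), apoptosis (0.25, adjusted p = 0.237 with an estimated correlation) and migration receptors (0.25, adjusted p = 0.434 with an estimated correlation; Cd69, 2.54, from 3.95, below the median of all values). The rest were neutrophil markers (0.19, adjusted p = 0.265 with an estimated correlation), glycolysis (0.15, adjusted p = 0.483 with an estimated correlation) and, lower, conventional dendritic cell markers (-0.17, adjusted p = 0.321 with an estimated correlation). The nonclassical monocyte list differed by 0.08 (adjusted p = 0.409).

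The comparison of T cell-depleted secondary with primary infection asks whether the response without T cells returns to that of a first infection. The primary mice were not depleted of T cells. Earlier infection and T cell depletion therefore differ together here, and their effects cannot be told apart. Iigp1 rose by 2.88 (SE 0.33, adjusted p = 0.0158), from 4.73 ± 0.44 to 7.62 ± 0.64 (SD, n = 3 per group). It was the only gene called, with 815 at an unadjusted p under 0.05. Groups did not overlap for 7.40% of genes, where chance gives 10%. Cxcl10 differed by 1.88 (adjusted p = 0.459), and the remaining fixed genes by 1.47 for Il6, 1.44 for Cxcl9, 1.14 for Ifit1, 1.08 for Tnf, and 0.78 for Irf1. They were 0.46 for Il15, 0.42 for Il12b, 0.25 for Il1b, 0.25 for Nos2, 0.10 for Ifng, -0.35 for Ccr2 and -0.38 for Ciita. Without primary array 1 (539 genes at unadjusted p under 0.05), primary array 2 (2118), depleted array 2 (514) or depleted array 3 (1673), limma called 0 genes. So it did with median centring, with the minimum fold, with the 2 groups alone and with the 8 arrays without number 2, while array spread as a covariate, chosen after the data were seen, gave 11 and array weights gave 5104. Among lists 6 were called higher and 1 lower. With an estimated correlation 0 calls were left, and fry called 0 for a shift one way and 3 for change in either direction. Interferon gamma response genes were higher by 0.89 (adjusted p = 7.44e-11, and adjusted p = 0.161 with an estimated correlation; Iigp1 over all 21 genes and 8 adjusted over the list alone). The others were type I interferon genes (0.67, adjusted p = 0.467 with an estimated correlation), chemokines (0.54, adjusted p = 0.134 with an estimated correlation) and NF-kB targets (0.35, adjusted p = 0.907 with an estimated correlation). The last were inflammatory cytokines (0.34, adjusted p = 0.134 with an estimated correlation), nonclassical monocyte genes (0.26, adjusted p = 0.907 with an estimated correlation) and, lower, cell cycle genes (-0.12, adjusted p = 0.730 with an estimated correlation).

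The 63 genes called between secondary and primary infection were followed in the T cell-depleted group. The 52 higher genes had a median difference of 2.06 between secondary and primary infection and of 0.71 between T cell-depleted secondary and primary infection. The median share of the difference that was left was 35.3%. For the 11 lower genes these values were -1.67, -0.43 and 28.6%. The genes were chosen on arrays that also enter both other differences. In 100 simulations without any effect, genes chosen in the same way had a share of 50.9% left for the higher and 50.3% for the lower ones. Of the 52 higher genes all 52 were above the T cell-depleted group in secondary infection (48.16 simulated). In the T cell-depleted group, 49 were above primary infection (48.15 simulated). Simulated genes differ by noise alone, whereas the genes called here may hold real differences. Such simulations therefore cannot decide what the signs and the shares left mean. Only Iigp1 passed the test between T cell-depleted secondary and primary infection, and only Cnn3, Dnase1l3, Upp1 and Ceacam1 passed the test between the groups with and without T cells.

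**Figure D3:**
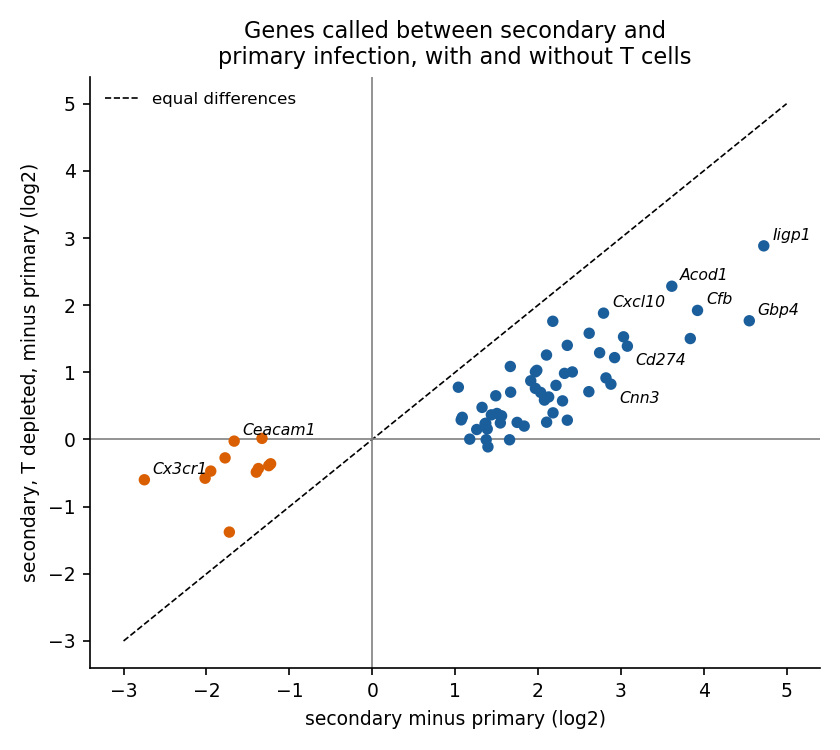
Each point is 1 of the 63 genes called between secondary and primary infection, with the log2 difference from primary infection in secondary arrays (horizontal) and in T cell-depleted secondary arrays (vertical); the dashed line marks equal differences. The 52 higher genes lie below the line, and Iigp1 goes from 4.72 to 2.88.

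Called genes were shared between comparisons. Of the genes higher in secondary than in uninfected arrays, 49 were also higher than in primary arrays (0.316 if the comparisons were independent), and 18 were also higher in T cell-depleted secondary arrays (0.115 if independent). Simulations of shared arrays alone gave 12.15 (highest 18) and 5.99 (highest 13). Of the lower genes, 10 (0.0177 if independent; 2.44 simulated, highest 5) and 1 (0.37 simulated, highest 1) were shared. All 3 genes called in primary infection, S100a8, Cxcl10 and Jun, rose in secondary infection as well (0.0182 if independent; 1.35 simulated, highest 3). These comparisons share 3 arrays, which cannot be split in parts of at least 2, so part of each overlap comes from the shared arrays. The simulated noise was independent between genes, whereas real genes vary together with the spread of an array's values. Simulated overlaps and correlations may therefore vary less than those of real arrays without any effect. Across genes, which are not independent replicates, the differences of secondary and T cell-depleted secondary from uninfected arrays had r = 0.704 where simulations of shared arrays alone gave 0.50. Their covariance exceeded the simulated one by 0.0374. For primary and secondary minus uninfected, r was 0.445 against 0.502 simulated, and the covariance exceeded the simulated one by 0.00670. For secondary minus primary and secondary minus T cell-depleted secondary, r was 0.668 against 0.50 and the excess covariance 0.0263. For primary and T cell-depleted secondary minus uninfected, r was 0.526 against 0.501 and the excess covariance 6.85e-04.

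Lists of monocyte identity and of most other cell types were not called in any of the 6 comparisons. In secondary minus uninfected arrays, mean differences were -0.14 for monocyte identity (adjusted p = 0.787), 0.15 for scavenger receptors (adjusted p = 0.613), and 0.02 for T cell markers (adjusted p = 0.744). They were 0.06 for NK cell markers (adjusted p = 0.751), 0.05 for B cell markers (adjusted p = 0.837), and 0.06 for plasmacytoid dendritic cell markers (adjusted p = 0.851). They were 0.01 for red pulp macrophage markers (adjusted p = 0.744), 0.04 for erythroid and platelet markers (adjusted p = 0.698) and 0.03 for stromal and endothelial markers (adjusted p = 0.756). Neutrophil markers differed by 0.14 (adjusted p = 0.259) and conventional dendritic cell markers by -0.23 (adjusted p = 0.0914). Cd209a, which belongs to the dendritic cell and scavenger receptor lists, fell by 1.49 (adjusted p = 0.00924). Klrk1, which encodes the activating receptor NKG2D and belongs to the NK cell list, rose by 1.87 (adjusted p = 0.0275). In 25 of 192 tests of a list in a comparison, the median, the mean and the test differed in sign, and 0 of these lists were called. In secondary minus uninfected arrays these were monocyte identity, cholesterol synthesis and the markers of T cells, plasmacytoid dendritic cells and stroma. Monocyte identity did so in secondary minus primary arrays as well (mean -0.33, adjusted p = 0.0755), and scavenger receptors in 4 comparisons.

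Arrays differed in the spread of their values. The SD of an array's log2 values ran from 1.45 (primary array 2) to 1.76 (primary array 1), and the array numbered 2 had the lowest SD in each of the 4 groups. Group means of this SD were 1.59 ± 0.11 in uninfected, 1.64 ± 0.17 in primary, 1.61 ± 0.06 in secondary and 1.60 ± 0.12 in T cell-depleted secondary arrays. Across the 12 arrays the first principal component, which held 34.1% of the variance, followed this SD (Pearson r = 0.993, Spearman rho = 1, each with a permutation p of 1e-05, the smallest that 100000 permutations can give), and r was 0.992 without the 2 farthest arrays.

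**Figure D4:**
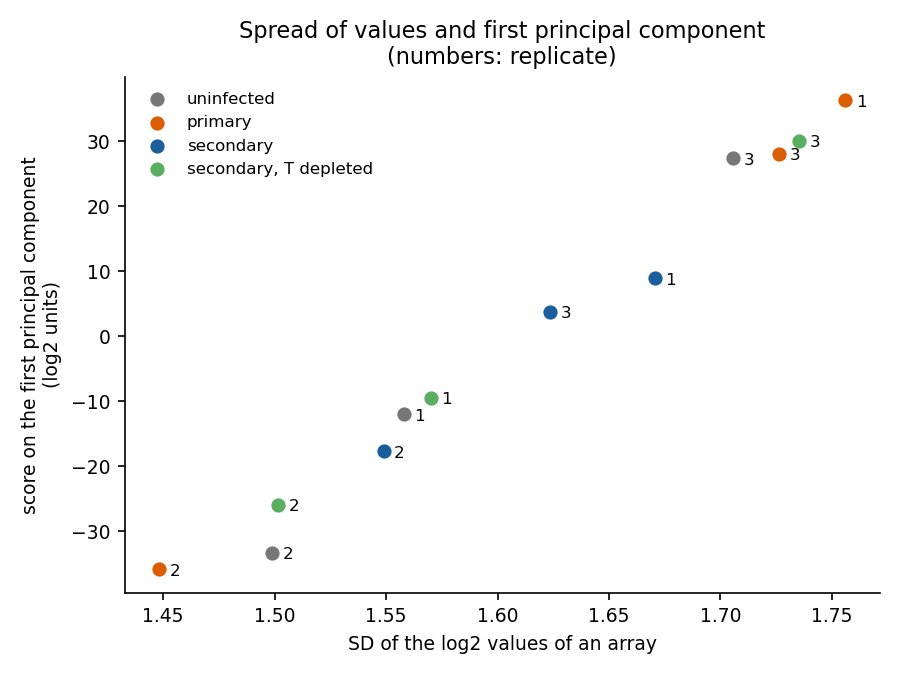
The SD of the log2 values of each array (horizontal) is plotted against its score on the first principal component in log2 units (vertical); points are the 12 arrays, coloured by group and marked with the replicate number. Arrays numbered 2 have the lowest SD of their group, down to 1.45 in primary array 2.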

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

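The comparison of the interferon gamma list with the type I interferon list, the comparison of induced lists with and without T cells, the tests of isolation days, the comparison of marker lists with lists of like expression and the fits with array spread as a covariate or without arrays numbered 2 were chosen only after results had been seen. Of the 9006 probe sets left out of the gene test, because they carry several gene symbols or none or are a gene's weaker probe set, some changed between groups in the fit of all probe sets together, a signal in data the comparisons above do not use. In primary minus uninfected arrays 7 were called, all 7 higher and with several symbols. In secondary minus uninfected arrays 25 were called, 21 of them higher (10 with several symbols, 11 with none and 4 a weaker probe set). In secondary minus primary arrays 26 were called, 16 of them higher (19, 6 and 1). Secondary minus T cell-depleted secondary arrays gave 1, higher and without a symbol, and T cell-depleted secondary minus uninfected arrays gave 1, higher and with several symbols.

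The interferon gamma list, with Gbp4, Iigp1 and Cd274, was higher in secondary than in T cell-depleted secondary arrays by 1.12. A difference in the spread of array values is argued against, since mean spread was alike in these groups (1.61 ± 0.06 and 1.60 ± 0.12). With that spread as a covariate the difference was 1.09 (camera adjusted p = 1.07e-20, and 1.94e-28 to 0.0706 over the alternatives, the last from fry). Groups so alike in spread left the covariate little to change, so that fit adds little. Under an equal weakening of every induced program, the share lost by the interferon gamma list would lower the type I interferon list by 0.43. That list differed by 0.032 (median 0.03, SD over genes 0.33). Its values varied between mice (7.60 ± 0.25 and 7.56 ± 0.45, SD, n = 3 per group), so this list alone cannot decide. The interferon gamma mean minus the type I mean was higher in every secondary than in every depleted array, by at least 0.738. Equal weakening would give 0.688 between the group means, where 1.09 was observed (exact permutation p = 0.1, the smallest possible). The 0.688 was derived from the share that the interferon gamma list lost in these same arrays. The type I list was set against it after the values were seen. With 3 mice per group, these values therefore cannot decide on an equal weakening. Of the 16 lists called higher in secondary than in uninfected arrays, 15 had lower means without T cells. Falls were 0.51 for MHC class I, 0.40 for antimicrobial effectors, 0.36 for MHC class II and 0.33 for inflammatory cytokines and for NF-kB targets. They were 0.32 for glycolysis and 0.27 for chemokines. Of its rise over uninfected arrays, the interferon gamma list kept 57.0% without T cells. MHC class II kept 19.7%, glycolysis 32.3%, MHC class I 33.1%, alternative activation 40.0%, oxidative phosphorylation 48.1% and the unfolded protein response 49.6%. The other lists kept more, from 61.3% for antimicrobial effectors to 124% for dissociation stress. So the interferon gamma list did not lose the largest share. A weaker response of many programs, by equal or unequal amounts, therefore stays open. So does a need for T cells at challenge, the biological explanation that the design names, for the interferon gamma response or for a broader one. Differences between isolation days and effects of the depletion other than the loss of T cells were not tested and stay open.

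The nonclassical monocyte list, with Ace and Cx3cr1, was lower in secondary than in T cell-depleted secondary arrays by -0.76. With array spread as a covariate the difference was -0.79 (camera adjusted p = 1.08e-11, and 1.08e-11 to 0.125 over the alternatives). Mean spread was alike in these groups (1.61 and 1.60), which argues against spread as the cause and left the covariate little to change. A lower share of Ly6C-low monocytes among the sorted cells, which the labels describe as Ly6C-positive, cannot be told apart from a lower expression per cell. The 14 genes of the monocyte identity list outside the nonclassical list differed by a mean of -0.080 (median -0.03, camera adjusted p = 0.733, 6 of them positive). That is neither a rise nor a fall, and these genes are not restricted to classical monocytes. The most abundant genes of the list, Adgre4, Cx3cr1 and Nr4a1, were at 7.57, 5.77 and 7.44 with T cells and 8.42, 7.92 and 8.10 without, and 4 of its 13 genes are also in another list. The loss of T cells itself stays among the open explanations.

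The arrays numbered 2 had the narrowest spread of values in each of the 4 groups, and 1224 genes differed between them and the other arrays of their groups. In 4 bins of expression from dim to bright, the median difference was 0.21, 0.20, 0.11 and -0.29. Cells of another type are a candidate source: the criterion written before the test was met, since the T cell marker list was higher in arrays numbered 2 by 0.25 (adjusted p = 0.0204). Lists of like expression, added after that result was seen, rose by 0.15 on average, and the T cell list lay at their 95.9th percentile. The bound for that comparison, the 97.5th percentile, was also set after the result, and without it the criterion alone would have counted in favour of such cells. The list's most abundant genes were dim (Cd3e 4.93 against 4.59, Bcl11b 4.79 against 4.48). The NK cell markers (0.23, 96.2nd percentile) and B cell markers (0.25, 94.8th percentile) moved alike. Such cells, which the sort excluded by surface markers, cannot be told apart from the compression of all dim genes (1 of the 14 T cell genes is also in another list). A first test of isolation days, over all arrays of the same number, had a lowest correlation of -0.229, read as evidence against 1 day per number. It was replaced after that result by a test of the arrays numbered 2 alone. A day shared by these cannot be told apart from the shared spread. Deviations of the arrays numbered 2 correlated at 0.293 to 0.517, which a shared day would give and the shared narrow spread gives too. Without the part that follows the spread they were at -0.406 to -0.030, but taking that part out itself pushes these arrays apart, so the values decide nothing. No biological explanation was tested.

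The calls were set against the other splits of the same arrays, in which 3 arrays against 3 make 10 splits, too few for a share under 0.05. In secondary minus uninfected arrays, with Cxcl10 and Iigp1, 1 of the 10 splits, the real one, gave as many genes (153, highest other 0). The real split was also the only 1 for secondary minus primary (63, highest other 0), secondary minus T cell-depleted secondary (4, highest other 1) and T cell-depleted secondary minus uninfected (20, highest other 1). In primary minus uninfected arrays 2 splits gave as many (3, highest other 1204), and in T cell-depleted secondary minus primary arrays 2 did (1, highest other 1113). The 1204 genes came from primary arrays 1 and 3 with uninfected array 3 against the rest, and the 1113 from depleted arrays 1 and 2 with primary array 2 against the rest, which points to a structure of the samples that follows the spread of values and not the groups. For the F test 1 of 100 splits gave 84 genes, the real one, and the highest other gave 55. That makes chance an unlikely source of the count, although 100 splits can give no share below 1 in 100.

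Lists called at camera's preset correlation were often matched by other splits. As many lists as in the real split came from 4 of 10 splits in primary minus uninfected (13, highest other 21), 2 in secondary minus uninfected (17, highest other 17), 6 in secondary minus primary (13, highest other 22), 4 in secondary minus T cell-depleted secondary (11, highest other 18), 4 in T cell-depleted secondary minus uninfected (16, highest other 17) and 7 in T cell-depleted secondary minus primary arrays (7, highest other 21). The calls that hold with an estimated correlation, such as the interferon gamma list with and without T cells (adjusted p = 0.0433), rest less on that preset.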

How the results depend on the processing

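The fits with array spread as a covariate, without the 4 arrays numbered 2, and of 11 arrays without primary array 2 were chosen only after the data were seen. Counts are given in the order primary minus uninfected, secondary minus uninfected, secondary minus primary, secondary minus T cell-depleted secondary, T cell-depleted secondary minus uninfected and T cell-depleted secondary minus primary; they were 3, 153, 63, 4, 20 and 1, and 84 by the F test. All 7 counts stayed within 1.5 times of these with the filter on dim genes, the mean of a gene's probe sets and the variance trend. Like counts need not hold the same genes. With the variance trend 126 of the 153 genes and 49 of the 63 genes were still called. Between secondary arrays with and without T cells, 3 of the 4 genes were. That fit called 5 higher and 0 lower genes, so that Ceacam1 was lost.

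With the replicate block the counts were 7, 349, 190, 26, 35 and 3, and 183 by the F test. The labels do not say that the replicate numbers pair the arrays. Deviations of same-number arrays correlated at -0.229 to 0.221 for number 1, 0.293 to 0.517 for number 2 and 0.0740 to 0.607 for number 3, above 0.1 in 13 of 18 pairs. For 7 of 12 arrays the best match had the same number, a hint from the data and not from the design. Since not every pair was above 0.1, the numbers were not taken as pairs. Median centring gave 0, 74, 28, 2, 11 and 0, and 33 by the F test, with 703 and 954 genes at an unadjusted p under 0.05 by limma where the count was 0. Quantile normalization gave 5, 244, 140 and 10 in the first 4 comparisons and 145 by the F test. Array weights gave 8098, 1170, 2271, 132, 754 and 5104, and 8564 by the F test. Under them lower genes outnumbered higher ones in primary minus uninfected (5211 and 2887) and secondary minus primary arrays (1272 and 999). The weights ran from 0.187 for primary array 2 to 6.66 for primary array 3, so a few arrays decide that fit, and under it the median of all genes was -0.11 in primary minus uninfected, 0.10 in secondary minus primary and 0.11 in T cell-depleted secondary minus primary arrays. Array spread as a covariate gave 6, 568, 348, 61, 50 and 11, and 335 by the F test, with 295 higher and 273 lower genes in secondary minus uninfected arrays. In these settings the cause was not tested.

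The test against a minimum fold of 1.5, stricter by construction, gave 0, 49, 15, 0, 10 and 0, with 46, 83 and 37 genes at an unadjusted p under 0.05 where the count was 0. With all probe sets tested together primary minus uninfected arrays gave 10, of which 7 are probe sets outside the gene test. With 2 groups only, which leaves fewer arrays to estimate the variance, primary minus uninfected gave 1, secondary minus T cell-depleted secondary 0 (910 at an unadjusted p under 0.05) and T cell-depleted secondary minus primary 0 (635). With 8 arrays, number 2 left out, these last 2 gave 0 (1121 and 1283), and 1 of the 3 genes of primary minus uninfected, 109 of the 153 and 34 of the 63 genes were shared, the last comparison having 41 higher and 48 lower genes. Without primary array 2, secondary minus T cell-depleted secondary gave 13. The F test was not run for the minimum fold or the 11 arrays.

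With each array left out in turn, the 2 arrays left in a group being assumed to vary like the others, primary minus uninfected gave 0 (without uninfected arrays 1 or 2, or primary array 3; 1 without primary array 1) to 13 (without primary array 2). Secondary minus uninfected gave 68 (without uninfected array 1; uninfected array 2 gave 99, secondary array 1 gave 93, secondary array 3 gave 96) to 131 (without secondary array 2). Secondary minus primary gave 29 (without primary array 3; primary array 1 gave 37, secondary array 1 gave 40, secondary array 3 gave 39) to 91 (without primary array 2). Secondary minus T cell-depleted secondary gave 0 (without secondary array 1 or depleted arrays 1 or 2; secondary arrays 2 and 3 gave 1 each) to 12 (without depleted array 3). T cell-depleted secondary minus uninfected gave 13 (without uninfected array 1, depleted array 1 or depleted array 3) to 17 (without depleted array 2). T cell-depleted secondary minus primary gave 0 (without primary arrays 1 or 2, or depleted arrays 2 or 3) to 1. The F test gave 49 (without secondary array 3; uninfected array 1 gave 50, secondary array 1 gave 53) to 103 (without primary array 2). Fewer arrays lower the counts by construction; why leaving out primary array 2 or depleted array 3 raised them, the cause was not tested.

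Of the tests of named genes under an alternative, 2452 kept their direction and side of the threshold, 307 lost and 54 gained the call, and 0 called genes reversed. The kept ones include 26 whose sign changed where neither value was called. Ceacam1, called between secondary arrays with and without T cells, lost its call without any 1 of the 6 arrays of those groups. The largest of these differences in size was -1.72, without secondary array 1, and the smallest was that without secondary array 3. For lists, 317 were the same (3 with a changed sign, neither called), 162 lost and 1 gained the call, the nonclassical monocyte list in primary minus uninfected arrays with array spread as a covariate. The losses were 60 with fry, 57 of the 77 calls with an estimated correlation, 16 with the spread covariate, 16 with 8 arrays, 9 with the dim filter and 4 with the replicate block. Arrays give no depth, and values near the median of 4.08 are close to background.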

Other observations

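The histone list and its tests were chosen only after the values were seen, and so were the genes of the next paragraph. Several genes outside the lists changed in secondary infection. Il12rb2, which encodes a chain of the interleukin-12 receptor, rose in secondary minus uninfected arrays by 1.42 (SE 0.22, adjusted p = 0.00675), and Il18rap, a chain of the interleukin-18 receptor, rose by 1.76 (SE 0.32, adjusted p = 0.0209) from 3.96, below the median of all values (4.08). Ifngr1, the ligand-binding chain of the interferon gamma receptor, fell by 1.78 (SE 0.36, adjusted p = 0.0383). The sterol hydroxylase gene Ch25h rose by 1.57 (adjusted p = 0.0163) from 3.44, also below that median, the serum amyloid gene Saa3 by 3.47 (adjusted p = 0.00836), the macrophage enzyme gene Lacc1 by 3.47 (adjusted p = 4.61e-04) and the cyclin gene Ccnd2 by 2.61 (adjusted p = 2.00e-05).

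Relative to primary infection, Ccnd2 (2.32, adjusted p = 2.11e-04), Lacc1 (2.13, adjusted p = 0.0331), Ch25h (1.66, adjusted p = 0.0202) and Il12rb2 (adjusted p = 0.00806) rose in secondary infection. Il18rap (1.22, adjusted p = 0.194), Saa3 (0.55, adjusted p = 0.898) and Ifngr1 (-1.71, adjusted p = 0.0767) did not pass. Between secondary arrays with and without T cells none of these passed, at 1.66 for Ch25h (adjusted p = 0.0726), 1.34 for Ccnd2 (adjusted p = 0.0529), 1.12 for Il12rb2 (adjusted p = 0.156) and -1.34 for Ifngr1 (adjusted p = 0.538). The others were Il18rap (1.28) and Lacc1, each with an adjusted p of 0.470, and Saa3 (adjusted p = 1.00). In T cell-depleted secondary minus uninfected arrays Ccnd2 passed (1.27, adjusted p = 0.0238). The values of the other 6 were -0.10 for Ch25h, 0.30 for Il12rb2, -0.44 for Ifngr1, 1.98 for Lacc1 (adjusted p = 0.113), 2.35 for Saa3 (adjusted p = 0.319) and 0.48 for Il18rap, which did not pass.

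Histone genes formed a further pattern. The 31 measured histone genes, taken by symbol, were higher in primary than in uninfected arrays by a mean of 0.55 (25 of 31 positive, 0 called over all genes by limma; camera adjusted p = 3.08e-15, and 0.0669 with an estimated correlation) and lower in secondary than in primary arrays by -0.53 (5 of 31 positive, H1f2 called; camera adjusted p = 6.04e-10, and 0.151 with an estimated correlation). These means were 0.60 and -0.57 with median centring and 0.55 and -0.53 with quantile normalization. Their mean expression was 4.53 ± 0.14 in uninfected, 5.08 ± 0.27 in primary, 4.55 ± 0.15 in secondary and 4.72 ± 0.18 in T cell-depleted secondary arrays (SD, n = 3 per group). A symbol that is not a histone was dropped from the list after a look at its members. Histone genes are near-identical copies, and probes shared between them leave single genes uncertain.

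A candidate explanation was that histone genes follow the cell cycle. The cell cycle list differed by 0.21 and -0.17 in the same comparisons, with SDs over its genes of 0.20 and 0.29, and was called at camera's preset correlation in both (adjusted p = 2.60e-05 and 0.0194). The smaller ratio of its mean to that of the histones was 0.317, under the 0.50 set before that test, which counts against the explanation. A comparison of the shortfall with the spread of its genes was added after the result was seen. In secondary minus primary arrays that comparison could not have counted against cell cycling, since even no change would have stayed within 0.29. The spread over genes is also not the error of a mean. As the list moved the same way as the histones, a part played by cell cycling stays open. Other causes were not tested.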
